A study of Mus musculus with 40 samples.

How the data were processed

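Chromatin was immunoprecipitated from GFP-positive nuclei of mouse lung tumours (KN: FoxA1, FoxA2, TET3, TET2 and H3K27ac; KNF1F2: TET3, TET2 and H3K27ac) and from 2 tumour organoid lines (22E and KG1A: FoxA1), with 2 replicates per group. The 40 samples are 20 ChIP libraries, each with 1 peak list, and 20 inputs, which were not analysed here. Groups and replicate numbers were taken from the sample labels, although the peak names inside the TET2 lists carry replicates 2 and 3 in place of 1 and 2. The labels do not say that replicates came from separate animals or cultures, so the spread between them may be technical.

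The submitters' processing notes name Bowtie2 2.4.4, MACS2 2.2.7 and the build mm10, and state no role or order for them. Each deposited list holds peaks called in a single library, in the narrow layout of MACS2, or the broad layout for H3K27ac. Per peak the authors gave a score, about 10 times the -log10 q value, as deposited and not comparable between libraries. The deposited fold enrichment is a ratio of the peak over the caller's background within its own library. The deposited -log10 p and -log10 q values are those of the caller. The smallest -log10 q was about 1.01 in the broad lists, 2.04 in KN FoxA1 replicate 1 and about 1.30 in the other narrow lists. Scores, folds and q values are the authors' and were used only to rank, filter and describe peaks within a list.

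Peaks were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and bedtools 2.31.1. Peaks on the mitochondrial genome were set aside. For each mark the peaks of all 4 tumour libraries were merged where they overlapped by at least 1 bp. A merged region was KN-only with a peak in both KN and neither KNF1F2 libraries, KNF1F2-only in the reverse case and shared with a peak in all 4. The same counts were made for the other 2 ways of pairing the 4 libraries. A FoxA1, FoxA2 or other region of 1 group needed a peak in both of its replicates. A region without a called peak is not shown to lack the mark.

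Overlap with FoxA1 was compared between classes by two-sided Fisher exact tests across regions, adjusted by the Benjamini-Hochberg method over the 3 marks. Shares carry 95% Wilson intervals, which cover counting error only. Overlaps between targets were set against 100 random placements of the FoxA1 regions on the same chromosome (bedtools shuffle, one-sided). Genes came from a table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes; it holds no strand, exons or sequence. A gene was linked to regions in its body or within 10 kb, and gene lists were compared with all other genes that had a region of that mark by two-sided Fisher exact tests, adjusted over lists and classes. Sites of both FoxA1 and FoxA2 were compared with all other protein-coding genes. Regions and genes are not replicates, so these tests describe the peak sets and not the variation between animals.

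The 16 gene lists (228 genes, all found in the gene table) covered gastric, intestinal, liver, alveolar type 1 and type 2, airway, squamous and mesenchymal genes, gastrointestinal transcription factors, MAPK and Wnt targets, TET and DNMT genes, housekeeping genes, and markers of immune, endothelial, and fibroblast and smooth muscle cells. The lists, the region classes, the tests, except those said to have been added later, the rule for named genes and the first set of alternative settings were fixed before the data were examined. Named were Foxa1, Foxa2, Nkx2-1 and Hnf4a. From each list and mark, up to 4 members with the most KN-only and up to 4 with the most KNF1F2-only regions were named. The 10 regions of each class with the highest score in their weaker replicate, and the 10 highest-scoring sites of both factors, were named with the nearest protein-coding gene. Other genes are said to have been chosen after their values were seen.

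The alternatives were the stronger 50% of each list, a 50% overlap, equal numbers of peaks per library, other links of regions to genes, strata of region width, FoxA2 in place of FoxA1, shared in place of KNF1F2-only H3K27ac regions, pairing by replicate number, random gene lists matched on region number (10000 draws) and each library left out in turn. A search for the forkhead motif and distances from transcription start sites could not be run without sequence and strand; distances from either gene end took the place of the latter. The code was tested on simulated data of 16042 regions. It recovered all classes, an odds ratio of 6.21 where 6 was simulated, and called 6.5% of 200 sets without an effect at 0.05. Simulated regions lay apart and had a peak in every library of their class, so the classes had to be recovered. Missed peaks and merging of neighbouring regions were not simulated.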

Results

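The series profiled mouse lung adenocarcinoma by chromatin immunoprecipitation and sequencing (ChIP-seq), and deposited a list of called peaks for each of 20 ChIP libraries. The 20 input samples have no peak lists and were not analysed here. Tumours of mice with an oncogenic Kras allele and floxed Nkx2-1, called KN, were profiled for the transcription factors FoxA1 and FoxA2, the DNA demethylases TET3 and TET2, and the active histone mark H3K27ac. Tumours that also carried floxed FoxA1 and FoxA2, called KNF1F2, were profiled for TET3, TET2 and H3K27ac. Mice received tamoxifen at 120 mg/kg and GFP-positive nuclei were sorted from tumours 8 weeks later. FoxA1 was also profiled in the tumour organoid lines 22E and KG1A, which had been exposed to ethanol for 48 hours. Each group held 2 libraries.

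The lists give no read counts, so the sequencing depth is unknown and the number of peaks is the only measure of yield. KN FoxA1 libraries had 29009 and 21166 peaks, and KN FoxA2 libraries 20472 and 36505. H3K27ac libraries had 16163 and 19082 peaks in KN and 18572 and 21762 in KNF1F2. TET3 libraries had 14744 and 14549 peaks in KN and 17522 and 13640 in KNF1F2. TET2 libraries were the sparsest in KN, with 2487 and 1152 peaks, and differed most in KNF1F2, with 14684 and 2172. The organoid FoxA1 libraries had 57672 and 33409 peaks in 22E and 26771 and 45725 in KG1A. Of the regions found in either KN replicate, 53.6% were found in both for FoxA1, 35.1% for FoxA2, 63.3% for H3K27ac, 55.0% for TET3 and 18.9% for TET2. In KNF1F2 the share was 61.8% for H3K27ac, 55.1% for TET3 and 11.6% for TET2. It was 37.5% in 22E and 41.0% in KG1A.

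Foxa1, Foxa2 and Nkx2-1, the genes with floxed alleles, and Hnf4a, a nuclear receptor of gut and liver epithelium, were read in every comparison. The bodies of Foxa1, Foxa2 and Nkx2-1 each held 1 H3K27ac peak in every one of the 4 H3K27ac libraries, KNF1F2 included. H3K27ac peaks at these genes therefore gave no check of the deletion. The body of Hnf4a (chromosome 2, 163506811 to 163572907, mm10) held 3 and 2 H3K27ac peaks in the KN replicates and 0 and 1 in the KNF1F2 replicates. Within 10 kb of Hnf4a there were 3 and 5 TET3 peaks in KN and 0 and 0 in KNF1F2, next to 14 and 18 KN FoxA2 peaks.

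The first comparison set H3K27ac in KN against KNF1F2 tumours, which carried floxed FoxA1 and FoxA2, and asked which active regions were called in each. The trefoil factor genes Tff1 and Tff2, which encode secreted peptides of the gastric mucosa, had H3K27ac peaks in KN tumours alone. A window over these genes and neighbouring Tff3 (chromosome 17, 31115001 to 31176000) held 9 and 8 H3K27ac peaks in the KN replicates. It held 0 and 0 in the KNF1F2 replicates. Trp63, a regulator of basal and squamous epithelium, had the opposite pattern, with 1 and 0 peaks in KN and 10 and 15 in KNF1F2 over chromosome 16, 25673001 to 25903000. These windows were chosen after their values were seen.

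Across the genome, 3208 H3K27ac regions had a peak in both KN libraries and in neither KNF1F2 library (KN-only). Another 4076 had the reverse (KNF1F2-only), and 8758 had a peak in all 4 libraries (shared). Splitting the same 4 libraries by replicate number gave 96 and 502 such regions, and the crossed pairs gave 159 and 277. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, so no p was given to these counts. With 1 library left out, fewer libraries had to match. The KN-only count then rose to 6203 without KN replicate 1 and 4819 without KN replicate 2. The KNF1F2-only count rose to 9026 without KNF1F2 replicate 1 and 6393 without KNF1F2 replicate 2.

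Gastric genes carried KN-only H3K27ac regions far more often than other genes. Of 13 gastric genes with any H3K27ac region, 9 (69.2%) had a KN-only region, against 15.03% of other genes, and 0 had a KNF1F2-only region. The odds ratio was 12.7 (95% interval 3.91 to 41.4, two-sided Fisher exact adjusted p = 0.000509 over 32 list and class tests). The test takes genes as independent. The 10 kb windows of neighbours such as Tff1 and Tff2, or Gkn2 and Gkn3, overlap, so a region can count for several genes of a list. Tff2 had 4 KN-only regions. Gkn1 and Gkn2, which encode gastrokines of surface mucous cells, and Anxa10, an annexin of gastric epithelium, had 2 each. Muc1, which encodes a transmembrane mucin, had 1 shared region instead (chosen after its value was seen). The gastric odds ratio was 6.10 without KN H3K27ac replicate 1 (exact adjusted p = 0.0388) and 8.19 without KN replicate 2. With regions assigned to the nearest gene within 50 kb it was 23.2.

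Gastrointestinal transcription factors formed the other list past the threshold, with KN-only regions at 9 of 18 genes (50.0%; odds ratio 5.65, 95% interval 2.24 to 14.3; adjusted p = 0.00843, Fisher's exact test). Gata5, a zinc finger factor of foregut endoderm, Hnf4g, a relative of Hnf4a, and Spdef, a factor of mucus-secreting cells, had 2 KN-only regions each and no KNF1F2-only region. Hnf4a had 2 KN-only regions and 1 KNF1F2-only region. This list did not pass against random lists matched on the number of regions per gene (permutation adjusted p = 0.0640), while the gastric list did (adjusted p = 0.0128).

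**Figure D1:**
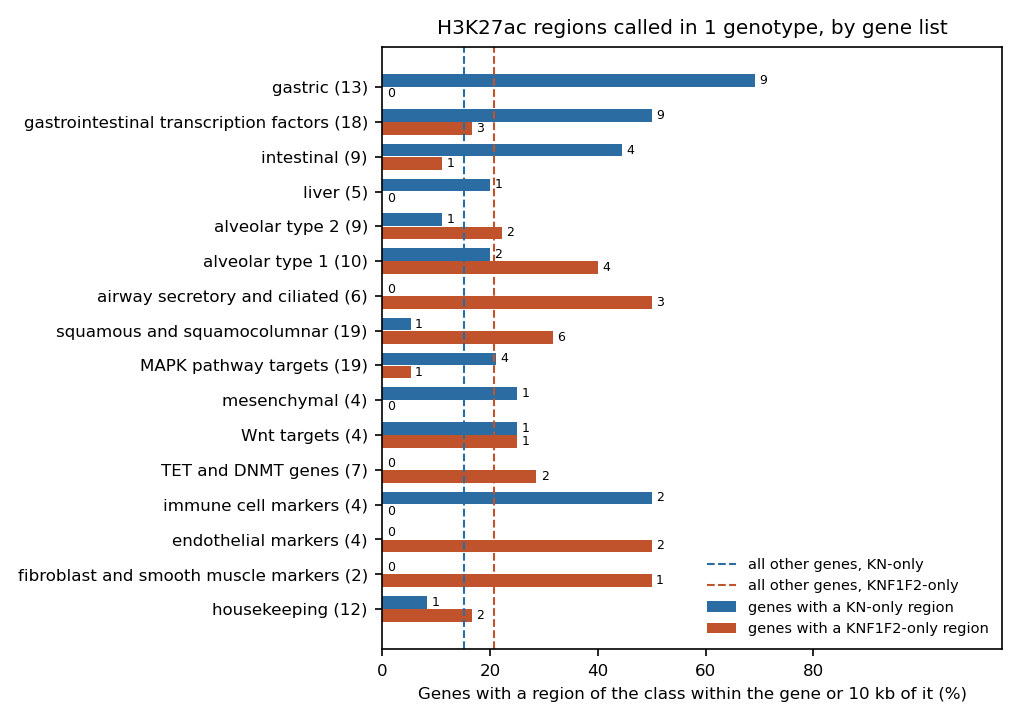
Bars give the percentage of genes of each list with an H3K27ac region called in KN only (blue) or KNF1F2 only (red) in the gene or within 10 kb of it, with the number of such genes beside each bar and the number of genes with any H3K27ac region in brackets. Dashed lines mark the percentage among all other genes; the gastric bar for KN reached 69.2% with 9 genes and its KNF1F2 bar stood at 0.

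None of the other 14 lists passed for KN-only regions, in the main analysis or under the alternatives. Intestinal genes had them at 4 of 9 genes (exact adjusted p = 0.368), among them Krt20, an intestinal keratin gene, and Vil1, which encodes a microvillus protein. Counts were 4 of 19 for MAPK pathway targets, 2 of 10 for alveolar type 1, where Clic5, a chloride channel family gene, alone had 6 KN-only regions, the most of any named gene, 1 of 9 for alveolar type 2, 0 of 6 for airway genes and 1 of 19 for squamous genes. Liver genes had 1 of 5, mesenchymal genes 1 of 4, Wnt targets 1 of 4, TET and DNMT genes 0 of 7 and housekeeping genes 1 of 12. Markers of cells outside the epithelium had 2 of 4 for immune cells, 0 of 4 for endothelium and 0 of 2 for fibroblasts and smooth muscle.

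KNF1F2-only H3K27ac regions passed for 0 of the 16 lists by Fisher's exact test, and for 0 at an unadjusted p under 0.05; other genes had such a region in 20.7% of cases. Trp63 had the most of any named gene, with 8 KNF1F2-only regions, and Ivl and Fat2, genes of stratified epithelium, had 2 each, within a squamous list of 6 of 19 genes (exact adjusted p = 0.821). Cav1, Pdpn and Cyp4b1, markers of alveolar type 1 cells, had 2 each among 4 of 10 genes, while Clic5 of the same list had 0 (exact adjusted p = 0.606). Airway genes had 3 of 6 (exact adjusted p = 0.589), with 2 regions at Aldh1a1 and 1 each at Scgb1a1 and Cyp2f2 of club cells. Tet3 itself had 4 KNF1F2-only regions and Dnmt3a, a DNA methyltransferase gene, had 3, as 2 of 7 TET and DNMT genes. The remaining counts were 3 of 18 gastrointestinal factors, 1 of 9 intestinal, 0 of 5 liver, 2 of 9 alveolar type 2, 1 of 19 MAPK, 0 of 4 mesenchymal, 1 of 4 Wnt and 2 of 12 housekeeping genes. Immune, endothelial and fibroblast markers had 0 of 4, 2 of 4 and 1 of 2. Under the alternatives, 2 lists passed for KNF1F2-only regions, each under 1 of them: airway genes with the stronger 50% of peaks (4 of 5; odds ratio 20.3, exact adjusted p = 0.0343) and squamous genes without KNF1F2 H3K27ac replicate 1 (14 of 19; 4.62, adjusted p = 0.0185).

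KN-only H3K27ac regions lay at FoxA1 sites. Of the 3208 regions, 69.9% overlapped a FoxA1 region of KN tumours (95% Wilson interval 68.3 to 71.5), against 7.34% of KNF1F2-only regions (6.57 to 8.18) and 41.5% of shared regions. The odds ratio of KN-only against KNF1F2-only regions was 29.3 (25.5 to 33.7), with a Fisher exact p below double precision. FoxA1 was mapped in KN alone, and KNF1F2-only regions by definition had no H3K27ac peak in KN. This contrast therefore favoured KN-only regions by design. Shared regions had peaks in KN as well. Against these the odds ratio was 3.27 (3.00 to 3.56), and 1.81 and 1.88 without KN H3K27ac replicates 1 and 2. FoxA2 sites did not part KN-only from shared regions in this way: 51.9% of KN-only and 53.4% of shared regions overlapped one (odds ratio 0.943, 0.870 to 1.02; two-sided Fisher exact p = 0.160). Shared regions lay within 1 kb of a gene end in 57.7% of cases, against 14.7% of KN-only and 18.3% of KNF1F2-only regions. FoxA2 regions of KN tumours lay there more often than FoxA1 regions (29.2% against 12.2%). The FoxA2 comparison with shared regions was not repeated away from gene ends or within quartiles of width. A FoxA2 difference within such strata was therefore not excluded. The odds ratio of 29.3 was 11.4 without KN H3K27ac replicate 1 and 10.4 without replicate 2. It was 10.6 with a 50% overlap and 15.3 with FoxA2 in place of FoxA1.

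**Figure D2:**
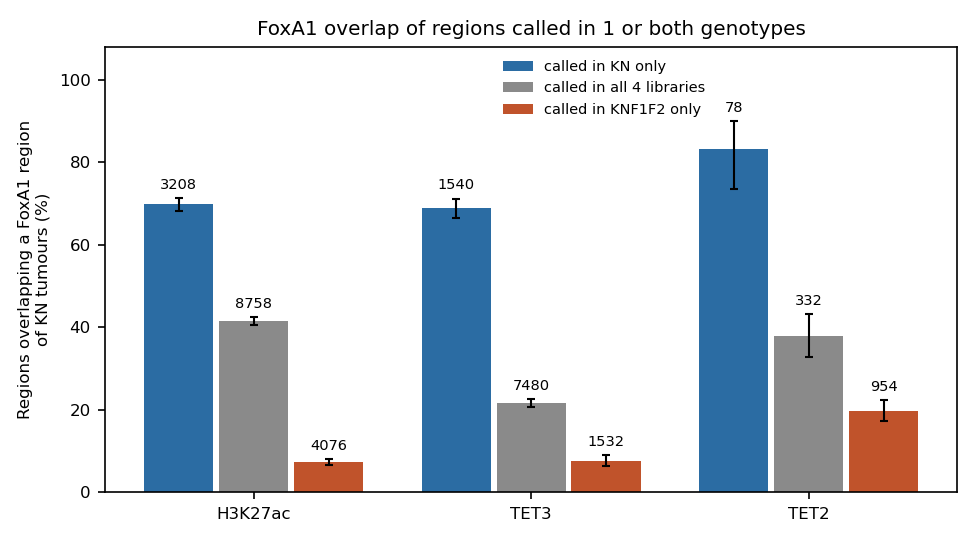
Bars give the percentage of H3K27ac, TET3 and TET2 regions that overlapped a KN FoxA1 region, for regions called in KN only (blue), in all 4 libraries (grey) or in KNF1F2 only (red); error bars are 95% Wilson intervals and numbers are regions. KN-only bars stood at 69.9%, 69.0% and 83.3%, and KNF1F2-only bars at 7.34%, 7.70% and 19.8%.

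Among the 10 KN-only H3K27ac regions with the highest scores in their weaker replicate, 8 overlapped both FoxA1 and FoxA2 regions. They included a 5481 bp region at the start coordinate of Hnf4a (chromosome 2, 163505882 to 163511362; 4.56-fold and 6.52-fold enrichment in the replicates). Others lay in Chad, a cartilage matrix protein gene, Ern2, Bcar1, Mrvi1, Celf4 and Cab39l, and 29411 bp from Sftpb, which encodes a surfactant protein. The top region was 281 bp wide with folds of only 3.10 and 3.24, lay 64721 bp from Cr2, and coincided with a TET2 region called in KNF1F2 only; a region in Cmtm7 also lacked both factors. The 10 KNF1F2-only regions ranked this way overlapped FoxA1 in 0 cases. They lay in or near Nfe2l3, Plin5, a lipid droplet gene, Hspa2, Wnt7b, a Wnt ligand, Trmt9b, Chil3, Tsku, Itm2b, Olfm2 and Cldn4, a tight junction gene.

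**Figure D3:**
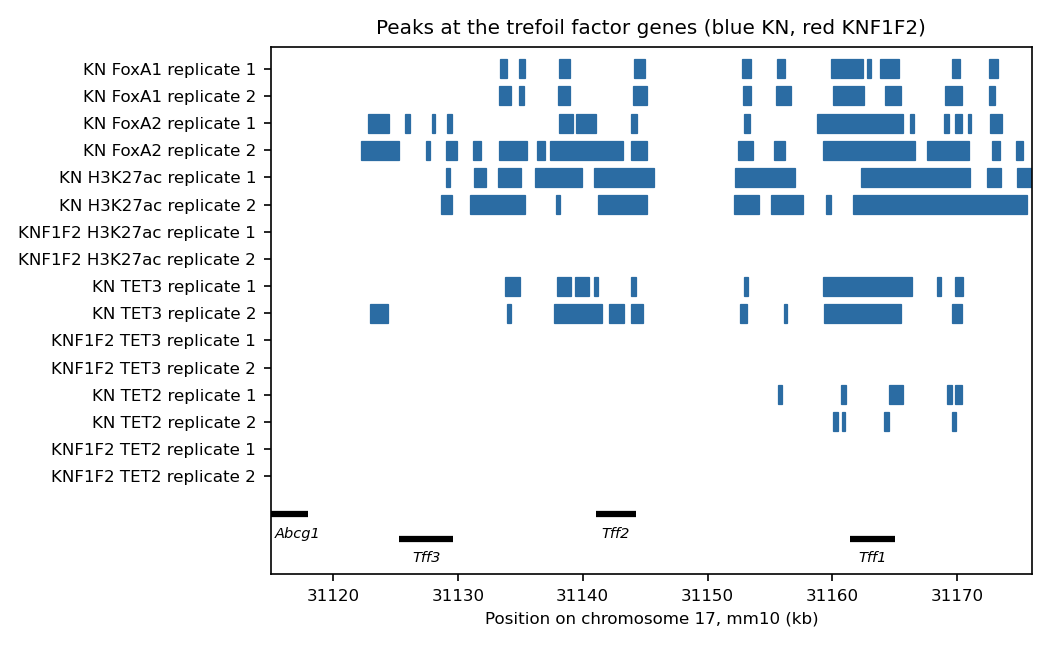
Each box is a called peak over the trefoil factor genes on chromosome 17 (mm10, position in kb), with 1 line per library, KN in blue and KNF1F2 in red. KN libraries had 8 to 9 H3K27ac, 9 TET3 and 4 to 5 TET2 peaks in the window, and the KNF1F2 libraries had 0 of each.

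The second comparison asked where TET3, which oxidises methylcytosine, was called in KN and in KNF1F2 tumours. The window over Tff1, Tff2 and Tff3 held 9 and 9 TET3 peaks in KN and 0 and 0 in KNF1F2. The highest-scoring KN-only TET3 region in the genome covered Tff1 (chromosome 17, 31159238 to 31166388), with 31.1-fold and 38.5-fold enrichment in the replicates. In KNF1F2, TET3 peaks were found at Trp63 (5 and 3, against 0 and 0 in KN).

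In all, 1540 TET3 regions were KN-only, 1532 were KNF1F2-only and 7480 were shared. The other pair splits of the 4 libraries gave 506 and 183 by replicate number and 212 and 477 for crossed pairs. Both genotype counts were above all of these. Both rose with a library left out, when fewer libraries had to match. The KN-only count was 3952 without KN replicate 1, 4149 without KN replicate 2 and 2333 without KNF1F2 replicate 1. The KNF1F2-only count was 2376 and 2321 without KN replicates 1 and 2, and 3439 and 6156 without KNF1F2 replicates 1 and 2.

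Of 14 gastric genes with any TET3 region, 8 (57.1%) had a KN-only region against 9.24% of other genes (odds ratio 13.1, adjusted p = 0.000156, two-sided Fisher exact test). The TET3 gene-list tests were added after the data were seen. Random lists matched on the number of regions per gene were not drawn for any TET3 list. A link to the number of TET3 regions per gene was therefore not excluded. Tff2 had 4 KN-only TET3 regions, Tff1 had 3, and Gkn3, a gastrokine gene, and Psca had 2 each. Gastrointestinal transcription factors had KN-only regions at 9 of 17 genes (odds ratio 11.1, exact adjusted p = 0.000156), led by Gata5 and Onecut2 with 7 each and Creb3l1 and Hnf1a with 3 each. Intestinal genes had 4 of 9 (odds ratio 7.83, exact adjusted p = 0.0408), with 2 regions at Krt20. The gastric odds ratio was 6.59 without KN TET3 replicate 1 and 5.65 without KN replicate 2. The intestinal call was lost without KN TET3 replicate 1 (odds ratio 2.92, exact adjusted p = 0.380), without KN replicate 2 (4.41, adjusted p = 0.159) and with the stronger 50% of peaks (3.42, adjusted p = 1). Its odds ratio was 26.1 without KNF1F2 TET3 replicate 1. Alveolar type 2 genes had KN-only TET3 regions at 1 of 13 (exact adjusted p = 1) and passed only without KN TET3 replicate 1 (10 of 13; odds ratio 12.2, exact adjusted p = 0.000500).

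KNF1F2-only TET3 regions were found at 8 of 18 squamous genes (44.4% against 13.3% of other genes; odds ratio 5.19, adjusted p = 0.0136, Fisher's exact test). Krt6a, a keratin gene of stratified epithelium, and Itgb4, a hemidesmosome integrin gene, had 4 each, Trp63 had 3 and Krt14, a basal keratin gene, had 2. MAPK pathway targets had them at 8 of 19 genes (odds ratio 4.72, exact adjusted p = 0.0156), with 1 each at the MAPK phosphatase genes Dusp4, Dusp5 and Dusp6. KN-only TET3 regions were at 4 of these 19 genes (21.1% against 9.27% of other genes; odds ratio 2.61, exact adjusted p = 0.373). The squamous call was lost without KN TET3 replicate 1 (odds ratio 3.35, exact adjusted p = 0.117), without KN replicate 2 (3.65, adjusted p = 0.0567) and without KNF1F2 replicate 2 (2.75, adjusted p = 0.428). It was also lost with equal numbers of peaks (exact adjusted p = 0.0698) and within 5 kb of gene ends (adjusted p = 0.150), and its direction turned with the stronger 50% of peaks (odds ratio 0.400). It was 9.70 without KNF1F2 replicate 1. The MAPK call was lost without KN replicate 1 (odds ratio 2.74, exact adjusted p = 0.239), KN replicate 2 (3.65, adjusted p = 0.0567) or KNF1F2 replicate 2 (2.83, adjusted p = 0.248), and with the stronger 50% of peaks (1.32, adjusted p = 1). Alveolar type 1 genes had 4 of 10 (exact adjusted p = 0.184), including Emp2 and Cyp4b1 with 2 regions each. Airway genes had 3 of 7 (exact adjusted p = 0.253), including Scgb1a1 with 4 and Cyp2f2 with 2.

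**Figure D4:**
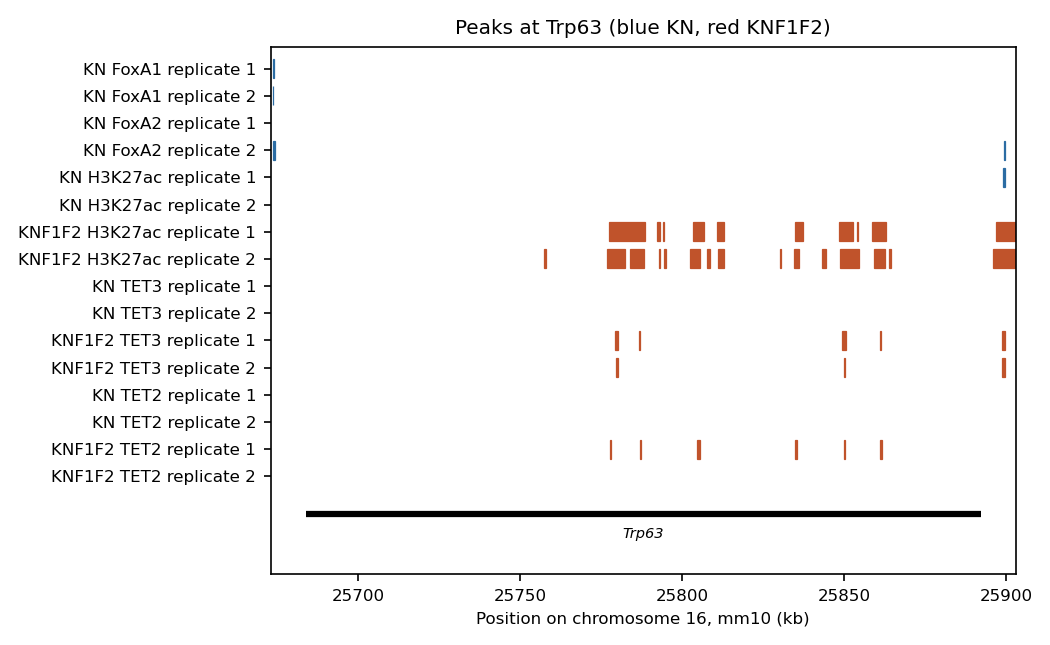
Each box is a called peak over Trp63 on chromosome 16 (mm10, position in kb), with 1 line per library, KN in blue and KNF1F2 in red. KNF1F2 libraries had 10 and 15 H3K27ac and 5 and 3 TET3 peaks in the window, the KN libraries had 1 and 0 H3K27ac and 0 and 0 TET3 peaks, and TET2 peaks came from KNF1F2 replicate 1 only.

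FoxA1 regions overlapped 69.0% of KN-only TET3 regions (66.6 to 71.2), 7.70% of KNF1F2-only regions (6.47 to 9.15) and 21.7% of shared regions. The odds ratio of KN-only against KNF1F2-only regions was 26.6 (21.4 to 33.1, two-sided Fisher exact adjusted p = 1.82e-295 over the 3 marks). As for H3K27ac, this contrast favoured KN-only regions by design, since KNF1F2-only regions had no TET3 peak in KN. Against shared regions the FoxA1 odds ratio was 8.02 (7.11 to 9.06). FoxA2 regions overlapped 77.5% of KN-only TET3 regions against 48.9% of shared ones (odds ratio 3.59). The odds ratio of 26.6 was 11.2 without KN TET3 replicate 1 and 9.83 without KN replicate 2.

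The strongest KN-only TET3 regions after Tff1 lay in Tmprss3, a serine protease gene next to it, Plk1, Mucl3, Eps8l3, Pllp, Onecut2, Depp1 and Myo5c, and 11538 bp from B4galnt1. All 10 overlapped FoxA2, and 6 also overlapped FoxA1. The strongest KNF1F2-only TET3 regions lay in Adamts1, a matrix protease gene (11.7-fold and 28.0-fold), Thbs1, which encodes thrombospondin (17.3-fold and 19.1-fold), and Plau, which encodes urokinase. Plin4, a lipid droplet gene, Cldn4, Tsku, Sox7, Cyp2d22, Rassf10 and Phlda3 made up the rest. Cldn4 and Tsku were among the strongest KNF1F2-only regions for H3K27ac as well.

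TET2, the third target compared, was called at far fewer regions. Tff1 had the most KN-only TET2 regions of the gastric list, with 2. Hnf1a, a factor of gut and liver, and Lgals4, an intestinal galectin gene, had 1 each. The window over Tff1, Tff2 and Tff3 held 5 and 4 TET2 peaks in KN and 0 and 0 in KNF1F2. KNF1F2-only TET2 regions numbered 1 each at Ager and Aqp5, markers of alveolar type 1 cells, Abca3 of alveolar type 2 cells and Sfn of squamous cells. The same held for Dusp4, Foxa3 of the gastrointestinal factors, Guca2a of the intestinal list and the housekeeping genes Gapdh and Rplp0. Vegfa, Epha2, Epha4 and Rnf43 also had 1 each. All of these genes had further TET2 regions of other classes, with 2 in all at Guca2a and 8 at Dusp4. Other genes with a TET2 region had a KNF1F2-only one in 11.8% of cases. By Fisher's exact test, added after the data were seen, 0 of 32 list and class tests passed, and 2 had an unadjusted p under 0.05 (gastric and intestinal, KN-only).

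In total 78 TET2 regions were KN-only, 954 were KNF1F2-only and 332 were shared. A split by replicate number gave 716 for replicates 1 and 42 for replicates 2, close to the larger genotype count, and the crossed pairs gave 4 and 194. The names inside the TET2 lists number the replicates 2 and 3 where the labels, which were followed, give 1 and 2, so what a TET2 replicate number stands for is uncertain. With 1 library left out, so that fewer had to match, the KN-only count was 270 and 824 without KN replicates 1 and 2. It was 266 without KNF1F2 replicate 1. The KNF1F2-only count was 12774 without KNF1F2 replicate 2. Equal numbers of peaks gave 161 and 195, the stronger 50% of peaks 40 and 492, and a 50% overlap 489 KNF1F2-only regions.

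FoxA1 regions overlapped 83.3% of KN-only TET2 regions (73.5 to 90.0), 19.8% of KNF1F2-only regions (17.4 to 22.5) and 38.0% of shared regions. The odds ratio of KN-only against KNF1F2-only regions was 20.2 (10.9 to 37.5, two-sided Fisher exact adjusted p = 3.51e-30 over the 3 marks). This contrast favoured KN-only regions by design in the same way. Against shared regions the odds ratio was 8.17 (4.33 to 15.4). The odds ratio of 20.2 was 4.32 and 4.20 without KN TET2 replicates 1 and 2. It was 7.34 without KNF1F2 TET2 replicate 1 and 12.2 without KN FoxA1 replicate 2. With equal numbers of peaks it was 6.16, and with FoxA2 in place of FoxA1 it was 12.2. The strongest KN-only regions lay in Zfpm1 (chromosome 8, 122306308 to 122308171; 8.26-fold and 10.97-fold), Cant1, Mucl3, Myo5c, Tmprss3, Rap1gap and Cfap69, and near Kif12, Parp11 and Asb7. All 10 overlapped FoxA1. The strongest KNF1F2-only regions were 283 to 931 bp wide. They lay in Gphn, Camk1d, Abcc5 and Lpcat3, and between 8238 bp (Rimbp3) and 372430 bp (Csmd1) from the nearest gene for Rimbp3, Pycr2, Ly6c2, Zfand3, Cr2 and Csmd1, and 2 of the 10 overlapped FoxA1.

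The third question was where FoxA1 was found in KN tumours relative to FoxA2, the TET proteins and H3K27ac. FoxA1 was found in both replicates at 17336 regions, of which only 12.2% lay within 1 kb of a gene end, against 29.2% for FoxA2, 65.7% for TET3 and 43.7% for H3K27ac. FoxA2 overlapped 52.1% of FoxA1 regions, H3K27ac 45.2%, TET3 18.4% and TET2 1.52%. The mean shares over 100 random placements were 1.26%, 1.71%, 0.798% and 0.0369%. Each observed share had a one-sided permutation p of 0.0099, the smallest that 100 placements can give. Placements here and for the organoid lines below fell anywhere on the chromosome. They were not limited to accessible chromatin, so a share above them does not set FoxA1 apart from other peak sets. In the other direction, FoxA1 overlapped 60.5% of FoxA2, 48.0% of H3K27ac, 30.1% of TET3 and 44.8% of TET2 regions. The FoxA2 share was 78.8% without KN FoxA2 replicate 1, and the TET2 share was 2.49% and 5.58% without KN TET2 replicates 1 and 2. The stronger 50% of peaks lowered the shares to 10.2% for TET3, 30.1% for H3K27ac and 0.952% for TET2. The TET2 share was 3.61% with equal numbers of peaks and 0.972% with a 50% overlap.

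Regions of both FoxA1 and FoxA2 numbered 9035, and 22.0% of protein-coding genes had at least 1. Gastric genes had one in 11 of 17 cases (odds ratio 6.48, adjusted p = 0.00155, two-sided Fisher exact test), with 5 at Tff1 and 3 at Tff2. Gastrointestinal transcription factors had one in 14 of 22 (6.19, exact adjusted p = 0.000527), with 7 at Hnf1b, 6 at Hnf1a and 4 at Hnf4a. MAPK pathway targets had 11 of 19 (4.86, exact adjusted p = 0.00404), with 6 at Spred2, which encodes a MAPK inhibitor. Alveolar type 2 genes had 9 of 15 (5.30, exact adjusted p = 0.00664), with 3 at Sftpd, a surfactant protein gene, and 1 at Nkx2-1. Sites at Hnf1b and Sftpd were chosen after their values were seen. The alveolar type 2 call was lost without KN FoxA2 replicate 1 (odds ratio 3.75, exact adjusted p = 0.0692), with the stronger 50% of peaks (2.96, adjusted p = 0.216) and with equal numbers of peaks (3.57, adjusted p = 0.0574). The MAPK odds ratio was 8.24 without KN FoxA1 replicate 2. These tests set each list against all other protein-coding genes, including genes without any peak. Housekeeping genes also had such sites more often than other genes (50.0% against 22.1%, odds ratio 3.53). A general link to active genes was therefore not excluded, and lists matched on region number were not drawn for these sites.

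The remaining 12 lists did not pass for sites of both factors. Housekeeping genes had 6 of 12 (exact adjusted p = 0.0989) and passed without KN FoxA1 replicate 2 (7 of 12; odds ratio 4.11, exact adjusted p = 0.0499) and within 5 kb of gene ends (5 of 12; 4.71, adjusted p = 0.0449). Counts were 5 of 15 intestinal, 7 of 22 squamous, 3 of 11 airway, 2 of 12 alveolar type 1 and 2 of 14 liver genes. TET and DNMT genes had 3 of 9, Wnt targets 2 of 12 and mesenchymal genes 1 of 12. Markers of immune, endothelial and fibroblast cells had 1 of 16, 1 of 10 and 0 of 10. The highest-scoring sites of both factors included ones near Rplp1 (chromosome 9, 61808007 to 61809342; 22.4-fold to 106-fold in the 4 libraries), in Exph5, near Slco2a1, in Stab2, near Myl1 and in Rab27b. The top-scoring region, 1034996 bp from Lrrc4c, had folds of only 1.74 to 2.33 and a peak in 18 of the 20 libraries, and the ones near Alkbh8 and Gm2244 had a peak in 17. A peak in all 20 libraries, the FoxA1 and FoxA2 ones included, was found at 145 regions.

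The fourth comparison asked how far FoxA1 sites of KN tumours were found in the organoid lines. Hnf4a had FoxA1 peaks in every library, with 6 and 5 within 10 kb in the tumours, 4 and 3 in 22E and 1 and 4 in KG1A. Nkx2-1 had 3 and 1 in the tumours, 1 and 7 in KG1A and 0 and 0 in 22E. Foxa1 itself had 8 and 5 FoxA1 peaks in the tumours, 9 and 6 in 22E and 4 and 6 in KG1A. Of the 17336 tumour FoxA1 regions, 54.6% overlapped a 22E region and 70.8% a KG1A region, against 1.88% and 1.65% for random placements (one-sided permutation p = 0.0099 for both). The 22E share was 86.3% without 22E replicate 2.

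Gastrointestinal transcription factors passed for FoxA1 sites found in all 6 tumour and organoid libraries. Such sites numbered 8151, and 15 of 20 genes of this list had one, against 31.0% of other genes (odds ratio 6.67, adjusted p = 0.00324, two-sided Fisher exact test; this test was added after the data were seen). The call was lost with the stronger 50% of peaks (odds ratio 3.08, exact adjusted p = 0.250), and the odds ratio was 14.0 without 22E replicate 2. This was the 1 list and class that passed among sites of all 6 libraries, of tumours only and of both organoid lines only. The number passing was 2 without KN FoxA1 replicate 1, 4 without KN replicate 2, 2 and 3 without KG1A replicates 1 and 2, and 4 with either other link of regions to genes. Squamous genes had sites of both organoid lines that were absent from tumour lists at 7 of 20 genes (exact adjusted p = 0.0643), and MAPK targets had sites of all 6 libraries at 12 of 19 (adjusted p = 0.0643). Within 5 kb of gene ends both passed (exact adjusted p = 0.0351 and 0.0377). Without KN FoxA1 replicate 2 both passed too (odds ratios 4.73 and 6.57). Squamous genes also passed without KG1A replicate 2 (4.81), and MAPK targets with the nearest gene (exact adjusted p = 0.00379). Alveolar type 2 genes passed for tumour-only sites with the nearest gene (exact adjusted p = 0.00629) and without KN FoxA1 replicate 2 (odds ratio 6.54). Gastrointestinal transcription factors had tumour-only sites at 5 of 20 genes, against 5.91% of other genes (odds ratio 5.30, exact adjusted p = 0.0643). These passed with the nearest gene within 50 kb (7 of 21, odds ratio 7.83, exact adjusted p = 0.00379). They also passed within 5 kb of gene ends (5 of 20, odds ratio 12.7, exact adjusted p = 0.00586). Without KN FoxA1 replicate 1 the odds ratio was 5.32 and without KG1A replicate 2 it was 7.92, past the threshold in both. FoxA1 regions called only in tumours numbered 1183, and those called only in both organoid lines 2487. FoxA2 of KN tumours overlapped 69.2% of the sites found in all 6 libraries and 20.6% of the tumour-only sites. The sites of all 6 libraries were wider (median 1570 bp against 517 bp), and neither width nor peak strength was held equal here.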

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

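The difference between the organoid lines and its recalculation without single libraries were chosen after the data were seen, while the tests with equal numbers of peaks were set out before their results were known. FoxA1 regions of KN tumours were found less often in 22E than in KG1A, and a test of the difference itself set this result apart. Of 17336 tumour regions, 3878 were found in KG1A alone and 1055 in 22E alone, a difference of 16.3 percentage points (exact McNemar p below double precision, across regions). With every FoxA1 library at 21166 peaks the difference was 18.3 points (62.9% against 44.6% of 15411 regions), which argues against the number of peaks as its source. What stays open is a single library. Like for like, with equal numbers of peaks, the 22E libraries alone covered 67.0% and 50.1% of the regions. Both KG1A libraries covered more, 73.5% and 70.0%, which met the rule set beforehand against a single library as the source. The gap of 2.93 points between the lines was smaller than the spread of 16.9 points within 22E. That rule did not include this spread. A weaker 22E replicate 2 as the source of much of the difference was therefore not excluded, and a difference of the lines stays open as untested. The difference was 8.54 points without KN FoxA1 replicate 2, 27.7 without KG1A replicate 1 and -15.5 without 22E replicate 2, but the last 2 set all peaks of 1 library against regions found in both libraries of the other line and so favour the single library by construction.

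Peaks on the mitochondrial genome, which no comparison used, numbered 5 in KNF1F2 TET2 replicate 1, against 1 in KNF1F2 TET2 replicate 2, 1 in each KN TET2 replicate, 2 in KN FoxA1 replicate 1 and 0 in every other library.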

How the results depend on the processing

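Of 311 alternative values, 257 kept their direction and their side of the threshold or stayed within 1.5 times a count, 36 moved, 16 kept their direction but fell short of the threshold, and 2 reversed. Those for the TET3 and organoid gene lists, the difference between organoid lines, sites of both factors without single libraries, distances from gene ends, stricter q, crossed pairs, the comparison with shared regions and the hypotheses on paired marks and on FoxA2 were chosen after seeing the data. The FoxA1 odds ratios kept direction and call under every alternative run, from 10.4 to 35.2 for H3K27ac (15 alternatives), 9.45 to 35.4 for TET3 (15) and 4.20 to 26.1 for TET2 (16). All of these were against KNF1F2-only regions, a contrast that favours KN-only regions by design. The H3K27ac odds ratio against shared regions also kept direction and call, from 1.81 to 6.55 (11). So did all shares of FoxA1 regions against random placement, a weak test since placements were not limited to accessible chromatin. With a replicate block by sample number the odds ratios were 13.001, 9.45 and 4.90; numbers do not show which samples belong together (TET2 names and labels number them differently), and TET2 regions summed over pairs were 1526 and 14791 for same numbers and 2125 and 15367 for crossed ones. The stronger 50% of each list, which holds fewer peaks, gave 1467 KN-only and 1942 KNF1F2-only H3K27ac regions, 551 and 737 for TET3, and 40 and 492 for TET2. Equal numbers of peaks gave 161 and 195 TET2 regions, and a 50% overlap 489 KNF1F2-only ones; the cause was not tested. Leaving out 1 library, so that fewer libraries had to match, gave 3598 to 6203 KN-only and 4529 to 9026 KNF1F2-only H3K27ac regions, 1750 to 4149 and 2321 to 6156 for TET3, and 80 to 824 and 1050 to 12774 for TET2. Against random lists matched on region number, which were drawn for H3K27ac only, 1 list passed in place of 2. The cause was not tested. Gastric genes passed under all 8 other H3K27ac alternatives (odds ratio 6.10 to 23.2), all 8 for TET3 (5.65 to 38.8) and all 8 for sites of both factors (4.58 to 7.75). The squamous TET3 odds ratio reversed to 0.400 with the stronger 50% of peaks (exact adjusted p = 1; over its alternatives 0.400 to 9.70), and the cause was not tested. The difference of KG1A and 22E reversed to -15.5 points without 22E replicate 2 and ranged up to 27.7 without KG1A replicate 1, where all peaks of 1 library were set against regions of both libraries of the other line, which favours the single library by construction. The forkhead motif and start-site alternatives were not run, since sequence and strand were not used here. Depth is unknown, so a missing peak does not show a missing mark, and 2 libraries per group allow no p below 0.333 by exact permutation.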

Other observations

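The counts of regions found in all 3 marks, the tests of TET3 with H3K27ac and of FoxA1 regions with and without FoxA2, and the alternatives of both were added after the data were seen, the test of TET3 with H3K27ac before its own result was known; the other tests were set out before their results were known. Peaks of H3K27ac, TET3 and TET2 were called in the same genotype alone at a small set of places. At 21 places all 3 marks had KN-only regions, and all 21 overlapped FoxA1 and FoxA2. They included 1 over Tff1 and another 4506 bp from it, Mucl3, a mucin-like gene, 2 in Cfap69, 1 lying 15848 bp from Krt20, and Chad, Celf4, Smoc1, Tns1 and Fhl2. Another 21 places had KNF1F2-only regions of all 3 marks, of which 1 overlapped FoxA1 and 3 overlapped FoxA2. These included Cldn4, Klk10, which encodes a serine protease of stratified epithelium, Tsku, Gdf15, a stress-induced secreted factor, Plin4, and a place 24058 bp from Grhl3, an epidermal barrier factor. The genes outside the rule for named genes were chosen after their values were seen, and neither count was recomputed without KNF1F2 TET2 replicate 1, the library with the most TET2 peaks. FoxA1 and FoxA2 were mapped in KN alone, and KNF1F2-only regions by definition had no peak of their mark in KN. The contrast in FoxA1 and FoxA2 overlap therefore favoured KN-only places by design. Places with shared regions of all 3 marks were not counted.

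Some listed genes had regions of both TET3 and H3K27ac called in the same genotype, which was counted and not tested. The share among other genes was not computed, so these counts cannot be read as high or low. Since the windows of Tff1 and Tff2, or Gkn2 and Gkn3, overlap, 1 region can count for both genes. KN-only regions of both marks were found at 6 of 17 gastric genes (Tff2, Tff1, Gkn3, Ctse, Gkn2 and Vsig1) and 5 of 22 gastrointestinal factors (Gata5, Onecut2, Creb3l1, Hnf4a and Spdef), and at Fabp2 and Krt20 of the intestinal list, Ttr of the liver list, Vegfa of the alveolar type 1 list, Etv4 of the MAPK list and Itgam, an immune marker. KNF1F2-only regions of both were found at 3 of 22 squamous genes (Trp63, Fat2 and Krt5), 2 alveolar type 1 genes (Cav1 and Cyp4b1), Cyp2f2 of club cells, Dnmt3a and the housekeeping gene Ppia, and at 0 gastric genes.

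A hypothesis is that TET3 and H3K27ac, where both were called in 1 genotype at a place, may be called in the same one. Among TET3 regions called in 1 genotype, 526 KN-only regions overlapped a KN-only H3K27ac region and 7 a KNF1F2-only one, while 335 KNF1F2-only regions overlapped a KNF1F2-only H3K27ac region and 2 a KN-only one. The odds ratio of the same genotype in both marks was 12586 (95% interval 2599 to 60950), for places where both marks were called in 1 genotype alone. It fell to 1248 and 668 without KN TET3 replicates 1 and 2, 1217 and 1531 without KNF1F2 TET3 replicates 1 and 2, 1281 and 1818 without KN H3K27ac replicates 1 and 2, and 3139 and 1626 without KNF1F2 H3K27ac replicates 1 and 2. More TET3 regions overlapped H3K27ac shared by both genotypes, 582 (37.8%) of the KN-only and 408 (26.6%) of the KNF1F2-only ones, than H3K27ac of their own class (34.2% and 21.9%), so many TET3 regions called in 1 genotype lay in H3K27ac called in both. The test does not show whether either mark depends on the other.

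A further hypothesis is that FoxA1 sites without FoxA2 may lose H3K27ac more often than sites with both factors. Of FoxA1 regions with KN-only or shared H3K27ac, 43.5% of 2131 without FoxA2 and 31.5% of 5266 with FoxA2 were KN-only. Within classes of distance from gene ends the Mantel-Haenszel odds ratio was 1.55 (1.40 to 1.73), and over 11 alternatives it ranged from 1.15 to 1.67, lowest with a 50% overlap. Single classes gave 1.72 within 1 kb, 1.67 up to 10 kb, 1.56 up to 50 kb and 1.37 beyond. Peak strength was not held equal in this test. Its direction could be read beforehand from the H3K27ac classes. FoxA1 without FoxA2 lay at 23.4% of KN-only and 8.22% of shared regions, and both factors at 46.5% and 33.3%. Only the classes of distance were new.

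The overlap of KN-only H3K27ac regions with FoxA1, at Tff2 and Hnf4a among others, was weighed against technical sources. Within quartiles of region width the odds ratio against KNF1F2-only regions was 32.0 (27.6 to 37.0), and more than 1 kb from gene ends it was 30.8 (26.5 to 35.8). Both values keep the favour that the design gives to KN-only regions, since FoxA1 was mapped in KN alone. KN-only and KNF1F2-only regions were alike in median width (1687 and 1580.5 bp) and in the share within 1 kb of gene ends (14.7% and 18.3%), so stratifying had little to remove here. Shared regions differed more (2449 bp and 57.7%), and against these the odds ratio of 3.27 was 6.55 (5.90 to 7.27) within quartiles of width and 2.035 (1.83 to 2.26) more than 1 kb from gene ends. Distance from gene ends may thus account for part of the difference from shared regions. The odds ratio against shared regions was also 1.81 and 1.88 without KN H3K27ac replicates 1 and 2. More immune, endothelial or stromal nuclei in KNF1F2 could add KNF1F2-only regions without FoxA1 despite the sort for GFP. Of 36 markers of these cells only 10 had an H3K27ac region and 3 a KNF1F2-only one, with 2 at Acta2 of smooth muscle (odds ratio 1.64, 0.424 to 6.35), so this source and the loss of FoxA1 and FoxA2 cannot be told apart for KNF1F2-only regions on so few genes.

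More TET2 regions were KNF1F2-only (954) than KN-only (78), though Tff1 had 2 KN-only regions. With every TET2 library at the same number of peaks the counts were 195 and 161, a ratio of 1.21, so the number of peaks per library is a candidate source of most of the imbalance. KNF1F2 TET2 replicate 1 had 14684 peaks and the other 3 TET2 libraries 1152 to 2487. A difference in TET2 between the genotypes stays open as untested, since the number of peaks may itself follow the genotype or the library.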
